A study of Arabidopsis thaliana with 16 samples.

How the data were processed

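Roots of Arabidopsis thaliana seedlings, accession Columbia, were profiled on Affymetrix arrays after the root had been divided along its length into 4 zones. Per the labels' protocols, seedlings grew for 5 days before transfer, and about 15 roots were pooled per replicate. The lowest piece, zone 1, ended about 150 µm from the tip. Zone 2 reached a further 200 µm to the end of the meristem, zone 3 a further 200 to 300 µm to just below the first root hairs, and zone 4 a further 1 mm. The -Fe medium held 0.3 mM Ferrozine, an iron chelator, in place of the iron salt. The design had 8 groups (4 zones on standard and on -Fe medium) of 2 arrays each, 16 arrays in all. The labels disagree on the time after transfer. The sample descriptions give 1 h for the standard roots and 24 h for the -Fe roots, whereas the treatment protocol gives 24 h for both. The medium comparisons below therefore also compare 1 h with 24 h after transfer if the descriptions are right.

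The deposited values were array signal intensities on a linear scale, from 0.0213 to 17169, for 22810 probe sets. Per the submitters' processing notes they were made with MAS5, with the version and detection calls not given in the sources used here. The mean of the values between the 2nd and 98th percentiles lay close to 250 on each array (from 249.88 to 249.90 intensity units), as a global scaling of each array gives. Sample labels used biotin with a two-cycle amplification, per the labels' protocols. The number of arrays limits the precision. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these pools, part of which may be technical.

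The 64 Affymetrix control probe sets were left out, and the other 22746 intensities were transformed as log2(intensity + 7.73), the offset being the 20th percentile of all of them. A log2 difference on this scale understates the change of a dim probe set. No further normalization was applied. Probe sets above their array's own 40th percentile on at least 2 arrays were kept, which left 16505. Means of intensities below are linear, and log2 differences are differences of mean log2 values.

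Differences were tested with limma 3.58.1 in R 4.3.3, with 8 group means, a shared spread over all 16 arrays (8 residual degrees of freedom) and an intensity trend in the variance prior. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. The contrasts were -Fe minus standard medium in each zone and averaged over the zones, the 3 steps between neighbouring zones on standard medium, a moderated F test of whether the iron effect differed between zones, and a moderated F test over the 4 zones on standard medium. Overlaps of calls between zones were tested with Fisher's exact test, two-sided. Each zone had its own standard and its own -Fe arrays, so these overlaps shared no arrays, though all zones shared the estimate of the spread.

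Genes were named from the platform annotation given with the data, updated to RefSeq names of the TAIR10.1 assembly. Of the 22746 probe sets, 13513 were annotated to 1 gene, 503 to several and 8730 were not listed. Of the single-gene probe sets 13436 matched a RefSeq locus and 77 kept the older name. After the filter 9167 probe sets for 9091 genes remained. Probe sets with no single gene were tested but not named. For that reason several well known genes of iron uptake, regulation and storage were not analysed here by name. IRT1, FRO2, FIT, BHLH38, BHLH39, BHLH100, FER1 and FER4 were among them. Where several probe sets stood for 1 gene, the one with the highest mean log2 over all arrays was used. No genome build was named in the files, so no coordinates are given.

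The named genes followed a rule set before the data were examined, among probe sets annotated to 1 gene. For the averaged contrast they were the 10 largest increases and decreases past the threshold with 1 sign in all 4 zones. For each zone and each zone step they were the 6 largest increases and decreases past the threshold whose 2 and 2 arrays did not overlap. For the interaction they were the 8 smallest p-values. Up to 6 members of each gene list could be named as well, and BHLH101 and PYE always. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a contrast. Of 21 lists set before the data were examined (269 members, 33 measured), 5 had at least 3 measured members and were tested. They were iron regulators, coumarin synthesis, cell cycle, cell elongation and root hair genes. A second family of 16 lists was drawn up from the annotation once the files could be read and before any contrast was computed, and was adjusted on its own. It includes 15 measured iron-response genes taken from knowledge of published iron-deficiency responses, which may include studies of these samples, so the direction of that list is not independent evidence. The iron regulator and coumarin lists, though set earlier, also hold genes known from published work on the iron response. Their direction is not independent evidence either. The lists of the second family are not complete. That of beta-glucosidases leaves out BGLU42, and that of expansins EXPA7 and EXPA18, which belong to lists set earlier. Further lists, used in the closing section only, were drawn up after results had been seen.

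Whether replicate numbers pair the arrays was checked from the differences of replicate 2 and replicate 1. Within a zone, those of the standard and -Fe groups correlated across genes at 0.18 to 0.37, all 4 above 0.1. Between zones the correlations ran from -0.13 to 0.46, with 11 of 24 above 0.1. The pairing is therefore a hint from the data within zones, and nothing in the labels states it. Values from fits with the replicate number as a block are given beside a result where they move it by over 1.5 times.

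The fit was tested on simulated data for the 16505 probe sets, with 200 of them changed by known folds. The folds were set on the log2 scale used for the tests, which includes the offset. Changes of 2-fold, 4-fold and 8-fold were steps of 1, 2 and 3 on it. For a dim probe set such a step is a larger change in intensity, and a large fall may be out of reach. Recovery of the same folds in intensity would therefore be lower for dim probe sets. Noise was drawn independently for each probe set, with the same spread in all groups. The unequal spread of the real groups and the correlation between genes were not simulated, so recovery in the real data may differ. For the zone 4 comparison the fit recovered 24% of 2-fold, 74% of 4-fold and 96% of 8-fold changes on that scale. For the averaged comparison it recovered 76% of 2-fold, 96% of 4-fold and 100% of 8-fold changes. The alternatives set before the data were examined covered the offset, the normalization between arrays, the filter, the variance prior, the arrays in the fit, the replicate block, array weights, a 2-fold minimum, the set test, and each array left out in turn. A replicate block fitted separately for each zone was added after the pairing check.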

Results

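Root pieces from 4 longitudinal zones, on standard medium and on iron-deficient (-Fe) medium, were compared on 16 arrays, 2 per group. Median intensity per array ranged from 51.3 to 76.0 units at a common scaled mean. Replicates correlated across genes at r = 0.92 (zone 3, standard medium) to 0.97 (zone 2, -Fe medium). The SD of the log2 difference between replicates was largest in zone 3 on standard medium, at 0.83 against 0.50 to 0.66 in the other groups. The first principal component carried 70.4% of the variance between arrays and the second 13.1%. The series asked how the response to iron deficiency is laid out along the root. By the sample descriptions the standard roots were collected 1 h and the -Fe roots 24 h after transfer, so the medium effect may include time since transfer.

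**Figure D1:**
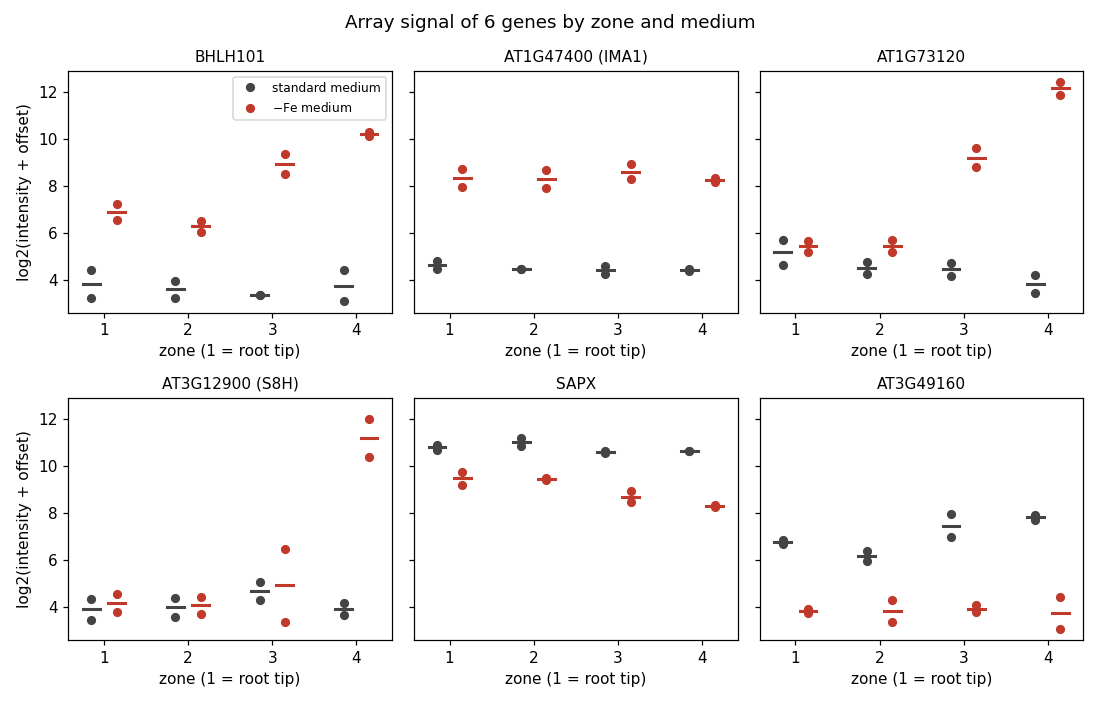
Array signal of 6 genes as log2(intensity + 7.73), by zone (1 is the root tip), for standard (grey) and -Fe medium (red). Points are the 2 arrays of a group and bars their mean. On -Fe medium AT1G47400 was higher in all 4 zones, BHLH101 in zones 1, 3 and 4, AT1G73120 in zones 3 and 4 and AT3G12900 in zone 4, while SAPX was lower in all 4 zones and AT3G49160 in zones 1, 3 and 4 (adjusted p under 0.05).

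Averaged over the 4 zones, several regulators of the iron response were higher on -Fe medium. BHLH101, a bHLH transcription factor of the iron-deficiency response, rose by 4.45 ± 0.25 (log2, SE, 8 against 8 arrays), from a mean intensity of 5.66 to 472. AT1G47400, which encodes the IRON MAN peptide IMA1, rose by 3.88 ± 0.17, and AT1G74770, encoding the E3 ligase BTSL1, by 3.02 ± 0.26 (2.83 on its other probe set). PYE, another bHLH factor of the iron response, rose by 1.53 ± 0.17 (adjusted p = 0.000257). AT5G05250 rose by 5.24 ± 0.30, from 39.8 to 1834 intensity units (adjusted p = 7.04e-07). Its order against BHLH101, whose standard signal lay below the offset, depends on the offset, since without one the differences were 5.60 and 6.16.

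Other named increases were the pectin methylesterase gene ATPMEPCRB (3.94), AT1G73120 (3.56), the metal transporter gene AT3G58060 (3.09), the glucosyltransferase gene UGT72E1 (3.07), AT3G56360 (2.85) and AT5G38820 (2.75). SAPX, the stromal ascorbate peroxidase, a heme enzyme, fell by 1.79 on the log2 scale (SE 0.11), from a mean of 1765 to 537 intensity units, and SIR, the sulfite reductase, which carries siroheme and an iron-sulfur cluster, fell by 1.53 (SE 0.12). PSAN, a subunit of photosystem I, fell by 2.22 (SE 0.40). AT3G49160 (-3.22 ± 0.23) and AT2G36885 (-2.29 ± 0.17) also fell. AT3G43670 (-1.96), AT2G41810 (-1.90), AT3G61870 (-1.60), AT1G68650 (-1.58) and AT5G51010 (-1.50) completed the 10. Of the 20 genes, 16 stayed past the threshold without any single array. PSAN was lost without zone 2 -Fe replicate 1 (adjusted p = 0.0512), AT2G41810, AT3G61870 and AT5G51010 without 7, 9 and 11 of the arrays. In all, 232 of 16505 probe sets passed (limma, adjusted p under 0.05), 110 higher and 122 lower. Median centring gave 152 higher and 84 lower, and a replicate block fitted per zone gave 444 calls. The count fell to 150 without zone 1 standard replicate 2, zone 2 -Fe replicate 2 or zone 4 -Fe replicate 1, and to 147 without zone 2 -Fe replicate 1.

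Among the lists, the iron regulators had 4 of 9 measured members higher over all probe sets and 5 adjusted over the list alone. Their median was 0.55 (camera, adjusted p = 8.55e-12, and adjusted p = 0.00695 with an estimated correlation). The coumarin synthesis genes had 2 of 4 members higher, over all probe sets and adjusted over the list alone, with a median of 0.91 (adjusted p = 0.000253, and adjusted p = 0.0418 with an estimated correlation). These 2 were BGLU42, a beta-glucosidase acting on coumarin glucosides (1.15 ± 0.23), and AT3G12900, the scopoletin 8-hydroxylase S8H (1.96 ± 0.42). The BGLU42 call was lost when any of 7 of the 16 arrays was left out, and the AT3G12900 call for any of 11. In the list of other iron-response genes, 11 of 15 were higher with a median of 2.47 (camera, adjusted p = 3.37e-32). None of these iron-related lists is independent evidence of direction. Cell cycle, cell elongation and root hair genes had no member past the threshold. Their medians were -0.27, 0.00 and -0.38 (adjusted p = 0.418, 0.743 and 0.172). For cell elongation the mean was -0.04 while the test pointed up, and quantile normalization turned the median to -0.03.

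In the root tip, zone 1, iron regulators were among the genes higher on -Fe medium. AT5G05250 rose by 4.83 ± 0.61 (log2, SE, 2 against 2 arrays), from an intensity of 33.5 ± 0.127 (SD, n = 2) to 1276 ± 744. AT1G47400 rose by 3.69 ± 0.34, AT1G74770 by 3.21 ± 0.51 and BHLH101 by 3.08 ± 0.50. AT2G41730 (3.43) and AT5G09570 (3.23) were higher as well. AT3G49160 (-2.94), AT2G36885 (-2.30) and SAPX (-1.32, from 1787 to 722 intensity units) fell. The other iron-response genes had 2 of 15 higher (median 0.27, adjusted p = 0.00014, and adjusted p = 0.272 with an estimated correlation). Of the 9 iron regulators measured, 3 rose, and also 3 adjusted over the list alone (camera, adjusted p = 9.89e-09, and adjusted p = 0.0181 with an estimated correlation). In all 18 probe sets passed, 14 higher and 4 lower. Of these 9 named genes only AT1G47400 stayed called when each array was left out in turn, with adjusted p up to 0.698 for the others, and the count fell to 3 without zone 1 standard replicate 1, to 4 without its replicate 2 and to 10 without zone 1 -Fe replicate 1. With the 4 zone 1 arrays alone limma called 0, with 520 probe sets at an unadjusted p under 0.05. These 520 are fewer than the share of 0.05 that chance alone would give among 16505 probe sets.

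In zone 2, which ended with the meristem, AT5G05250 rose by 5.11 ± 0.61 (SE), AT1G47400 by 3.82 ± 0.34 and AT3G56360 by 3.68 ± 0.37, the last from 143 ± 23.9 to 1916 ± 309 intensity units (SD, n = 2). AT5G09570 (2.67) and AT2G21640 (2.03) also rose, and AT2G36885 (-2.37) and SAPX (-1.58) fell. BHLH101 differed by 2.68 and did not pass in this zone (adjusted p = 0.112). Of the 9 iron regulators 1 passed over all probe sets and 3 adjusted over the list alone (camera, adjusted p = 4.36e-08, and adjusted p = 0.0228 with an estimated correlation). The other iron-response genes had 2 of 15 higher (median 0.67, adjusted p = 2.49e-07, and adjusted p = 0.0813 with an estimated correlation). The cell elongation list had a median of 0.60 with no member past the threshold (adjusted p = 0.0172, and adjusted p = 0.228 with an estimated correlation). In all 17 probe sets passed, 13 higher and 4 lower. AT1G47400 and AT3G56360 stayed called without any single array, with adjusted p up to 0.502 for the other 5 named genes. The count was 10 without zone 2 standard replicate 1, 6 without zone 2 -Fe replicate 1, 8 without its replicate 2, and 26 with array weights.

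In zone 3, below the first root hairs, BHLH101 rose by 5.58 ± 0.50 (SE), AT1G47400 by 4.19 ± 0.34 and AT5G05250 by 5.70 ± 0.61. AT1G73120 rose by 4.76 ± 0.44, from 14.7 ± 6.24 to 611 ± 237 intensity units (SD, n = 2). AT3G61930 (4.25) and the metal transporter gene AT3G58060 (4.14) followed. AT3G49160 (-3.52), AT2G36885 (-2.56), the pectin methylesterase gene AT5G51490 (-2.23), the glycosyl hydrolase gene GH9C3 (-1.93), SAPX (-1.90) and AT4G36050 (-1.77) fell. AT5G51490 (54.9 to 5.19 units) and GH9C3 (31.9 to 2.68 units) ended below the offset, so the size of their falls depends on it. Of the 9 iron regulators, 4 rose, PYE by 2.18 ± 0.33 among them, and 4 adjusted over the list alone (adjusted p = 1.68e-09, and adjusted p = 0.0139 with an estimated correlation). The other iron-response genes had 8 of 15 higher (median 2.85, adjusted p = 4.34e-30). In all 48 probe sets passed, 37 higher and 11 lower. The count was 125 without zone 3 standard replicate 1, and 23 without either zone 3 -Fe replicate or with array weights. With the 4 zone 3 arrays alone it was 14, and 5 of the 12 named genes (AT5G05250, BHLH101, AT1G73120, AT1G47400 and SAPX) stayed called without any single array.

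In zone 4, the uppermost piece, AT1G73120 rose by 8.31 ± 0.44 (log2, SE), from 7.20 ± 5.52 to 4655 ± 1244 intensity units (SD, n = 2), and AT3G61930 by 7.60 ± 0.56. AT3G12900 (S8H) rose by 7.27 ± 0.83, BHLH101 by 6.46 ± 0.50, UGT72E1 by 6.33 ± 0.62 and AT5G38820 by 5.64 ± 0.33. BGLU42 rose by 4.40 ± 0.45, and PYE by 2.61 ± 0.33. AT3G49160 (-4.06), SAPX (-2.35), the protein kinase gene WAG2 (-2.20), SIR (-2.11), AT1G24620 (-1.97) and AT2G36885 (-1.92) fell. AT1G24620 went from 31.0 to 2.01 units and so to below the offset, on which the size of its fall depends. SAPX went from 1605 ± 0.948 to 310 ± 14.9 intensity units, and SIR from 1183 ± 129 to 268 ± 4.50. Of the 12 named genes 10 stayed called without any single array, which left out AT1G24620 and AT2G36885.

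Of the 9 iron regulators, 5 rose in zone 4 and 5 adjusted over the list alone, with a median of 1.39 (adjusted p = 5.74e-12, and adjusted p = 0.00663 with an estimated correlation). Coumarin synthesis genes had 2 of 4 higher, also adjusted over the list alone (median 2.83, adjusted p = 1.1e-07, and adjusted p = 0.00706 with an estimated correlation). Of the other iron-response genes 11 of 15 rose (median 4.12). Of 109 cytosolic ribosomal protein genes, 7 fell over all probe sets, 79 fell adjusted over the list alone and none rose, with PGY1 (-0.94) and AT2G01250 (-0.97) among the 7. The median of all 109 was -0.70, and -0.70 and -0.57 under the 2 other scalings (adjusted p = 9.01e-37, and adjusted p = 0.25 with an estimated correlation). In all 153 probe sets passed, 112 higher and 41 lower. Median centring gave 132 higher and 14 lower. The count was 88 without zone 4 standard replicate 1 or 2, 63 without zone 4 -Fe replicate 1 and 81 without its replicate 2. The array control for 25S ribosomal RNA read 348 units in zone 4 standard replicate 2, against 2953 to 8609 on the other arrays. The actin 3' to 5' signal ratio, which can rise with RNA degradation, was 10.2 in zone 4 -Fe replicate 1, against 3.93 to 8.51 on the other arrays. The GAPDH and ubiquitin ratios of that array, 1.48 and 3.21, lay within those of the other arrays (1.40 to 2.17 and 2.64 to 6.45).

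**Figure D2:**
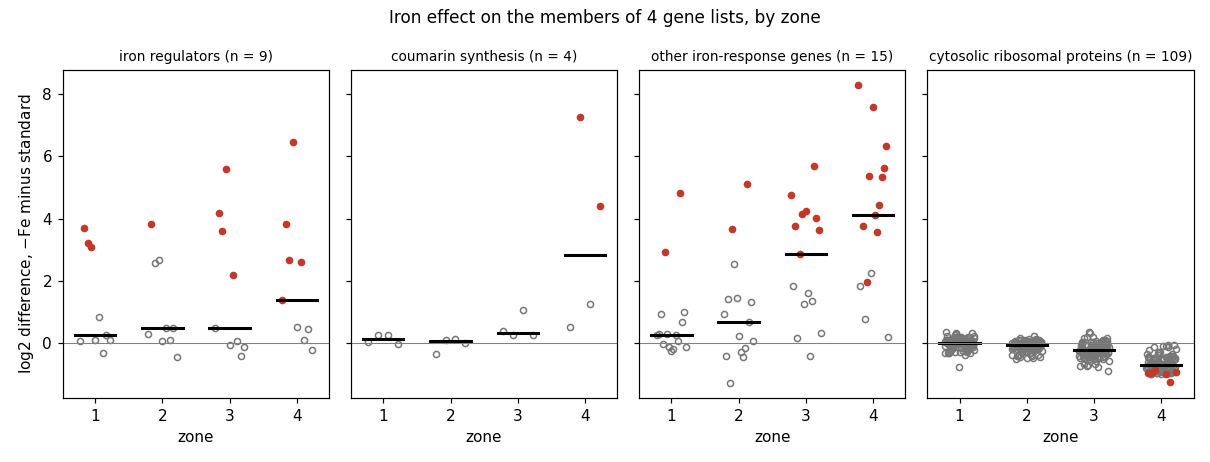
Log2 difference (-Fe minus standard medium) of each measured member of 4 gene lists, by zone. Filled red points passed the adjusted threshold, open grey points did not, and black bars are medians. The ribosomal protein median was -0.70 in zone 4, and that of the other iron-response genes 4.12.

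Whether the iron effect differed between zones was tested directly. It did for 20 probe sets, 8 of them with 1 gene (limma F test, adjusted p under 0.05). AT1G73120 differed by 0.27, 0.91, 4.76 and 8.31 in zones 1 to 4 (adjusted p = 0.000555), AT5G38820 by 0.69, 0.67, 4.00 and 5.64, and AT3G06890 by 0.87, 1.54, 2.45 and 5.26. AT3G61930 ran from -0.27 in zone 1 to 7.60 in zone 4. BGLU42 went from -0.05, 0.00 and 0.27 in the lower zones to 4.40 in zone 4 (adjusted p = 0.031). AT2G43610, AT3G48450 and AT4G10510 reached 4.35, 4.69 and 3.56 in zone 4. By contrast the difference of AT1G47400 ran from 3.69 to 4.19 over the zones (interaction adjusted p = 1.00), which does not show that it was equal. The replicate block raised the count from 20 to 35, while the block fitted per zone gave 19. Doubling the offset raised it to 31, and values without an offset lowered it to 10. It lay between 6 and 12 without any single array of zones 1, 2 and 4. AT1G73120, AT5G38820, AT3G06890 and AT3G61930 stayed called without any single array, while BGLU42, AT2G43610, AT3G48450 and AT4G10510 were lost without 12, 13, 12 and 15 of the 16.

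The zones were compared by the probe sets called in each. Zones 3 and 4 shared 33 higher probe sets (0.251 if independent) and 8 lower ones (0.0273). Zones 1 and 2 shared 10 higher (0.011) and 3 lower. The 12 comparisons of zone pairs and directions gave two-sided Fisher's exact p-values from 9.73e-70 to 3.28e-11, and the highest adjusted value was 3.28e-11. These tests take probe sets as independent, which they are not, and the zones shared 1 estimate of the spread. Of the probe sets called higher, 85 were so in 1 zone and 8 in all 4, and of those called lower, 36 and 3. AT5G05250, AT1G47400 and AT3G56360 were higher in all 4 zones, and SAPX and AT2G36885 lower. In all 43 probe sets were called in 1 direction in 2 or more zones. This count fell to 24 without zone 3 -Fe replicate 1, to 28 without its replicate 2 and to 15 when each zone was fitted on its own arrays.

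On standard medium, AT1G65570 fell from zone 1 to zone 2 by 6.50 on the log2 scale (SE 0.51), from 2280 to 14.2 intensity units, and AT1G50060 fell by 5.92 (SE 0.56). AT5G51470 (-3.47), AT4G26880 (-3.36), AT1G23160 (-3.36) and the glycosyl hydrolase gene GH9B6 (-3.34) also fell. AT1G05320 (3.56), AT4G11190 (3.53), AT2G43890 (3.45), AT1G63220 (3.21), AT1G57590 and the bHLH gene BIM1 (3.18) rose. Of 5 cell elongation genes 2 rose, COB (1.48 ± 0.20) and XTH19 (2.32 ± 0.69), and 3 adjusted over the list alone (adjusted p = 0.0217, and adjusted p = 0.304 with an estimated correlation). Of 3 cell cycle genes AUR1, an Aurora kinase gene, fell by 1.27 (SE 0.30), and 3 fell adjusted over the list alone (adjusted p = 0.0625). Among the lists drawn up later, 27 of 109 ribosomal protein genes fell (median -0.53, adjusted p = 2.23e-12, and adjusted p = 0.704 with an estimated correlation), and 7 of 30 mitosis and replication genes fell while 1 rose. Of 7 tubulin genes 4 rose, of 34 UDP-glycosyltransferase genes 8 rose and 2 fell, of 41 class III peroxidase genes 7 rose and 2 fell, and of 8 xyloglucan transglucosylase genes 2 rose. These 5 lists passed at adjusted p from 0.0023 to 0.0287, and with an estimated correlation at adjusted p of 0.704 or 0.706. The ubiquitin 3' to 5' signal ratio, a sign of RNA quality, was 5.43 and 6.45 on the standard zone 1 arrays, 3.63 and 4.79 in zone 2, 2.78 and 3.55 in zone 3 and 2.64 and 3.16 in zone 4. The actin ratio did not follow it, at 5.54 and 6.43, 4.87 and 3.93, 6.95 and 7.43, and 6.08 and 6.34. In all 3377 probe sets passed, 1754 higher and 1623 lower. The count was 983 without zone 1 standard replicate 1, 815 without its replicate 2 and 310 without zone 2 standard replicate 1. Of the 12 named genes AT4G11190, AT2G43890, AT1G23160 and GH9B6 were lost without some array (adjusted p up to 0.138).

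From zone 2 to zone 3, 8249 probe sets passed the threshold, 3774 higher and 4475 lower. The root hair list rose in all 3 measured members, which was also so adjusted over the list alone. EXPA7 and EXPA18, expansins of root hair cells, rose by 4.68 ± 0.80 and 5.02 ± 0.86, and SCN1 by 1.02 ± 0.26 (adjusted p = 0.0365, and adjusted p = 0.289 with an estimated correlation). Of 5 cell elongation genes 4 rose, XTH21 by 4.00 ± 0.52 among them, and 4 adjusted over the list alone (adjusted p = 0.0365, and adjusted p = 0.289 with an estimated correlation). The peroxidase genes AT3G49960 (5.85) and AT1G30870 (5.07), with AT3G23090 (5.46), AT3G45710 (5.28), AT5G24313 (5.15) and AT1G19900 (5.12), rose. AT3G06460 differed by -6.28, from 2442 to 27.1 intensity units, and AT3G20160 by -5.36, from 425 to 2.51 units and so to below the offset. Their order depends on the offset, since without one AT3G20160 differed by -7.40, more than AT3G06460. The other named decreases were AT3G49190 (-5.30), AT1G52070 (-5.09), AT2G41800 (-5.08) and AT1G52060 (-4.94). These 12 stayed called without any single array.

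Among the lists drawn up later, all 109 cytosolic ribosomal protein genes fell from zone 2 to zone 3 (median -1.78, adjusted p = 2.76e-31, and adjusted p = 0.377 with an estimated correlation). Of 30 mitosis and replication genes 23 fell and 2 rose, with TOPII, a DNA topoisomerase, at -2.51 and the histone gene HTB2 at -2.38. Of 8 extensin genes 6 rose, HRGP1 by 3.62 ± 0.62 among them, and of 41 class III peroxidase genes 18 rose and 5 fell. The adjusted p of the last 3 lists was 6.03e-06, 0.00285 and 0.00365, and with an estimated correlation it was 0.377 for each. Of 34 UDP-glycosyltransferase genes 16 rose and 3 fell, of 7 CYP71 genes 5 rose, of 13 glutathione transferase genes 7 rose and 1 fell, and of 8 xyloglucan transglucosylase genes 5 rose and 1 fell (adjusted p from 0.0065 to 0.0377, and adjusted p = 0.377 with an estimated correlation). Over this step the ubiquitin 3' to 5' ratio went from 3.63 and 4.79 to 2.78 and 3.55, and the actin ratio the other way, from 4.87 and 3.93 to 6.95 and 7.43. The count of calls was 5245 without zone 2 standard replicate 2 and 5469 on the arrays of zones 2 and 3 alone.

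From zone 3 to zone 4, GH9B13, a glycosyl hydrolase gene, fell by 4.89 (SE 0.40), from 1874 ± 1233 to 49.0 ± 12.7 intensity units (SD, n = 2). The SE comes from the spread shared by all groups, while the zone 3 standard replicates differed more than those of any other group. AT3G05150 (-4.64), AT5G12940 (-4.60), AT1G61840 (-4.51), the peroxidase gene AT4G16270 (-4.36) and AT1G14220 (-4.29) fell as well. Their order depends on the offset, as AT5G12940 and AT1G61840 ended below it, at 3.96 and 5.74 units. AT2G37750 (3.66), AT4G33550 (3.63), the subtilase gene ATSBT5.2 (3.60), AT5G43150 (3.42), AT1G05340 (3.29) and AT4G39675 (3.19) rose. Of 7 tubulin genes 3 fell, TUB5 (-2.62 ± 0.44), TUB1 and TUA6 (adjusted p = 0.000222, and adjusted p = 0.235 with an estimated correlation). Of 8 xyloglucan transglucosylase genes 4 fell, XTH16 by 3.12 and XTH19 by 3.84 (adjusted p = 0.0133, and adjusted p = 0.564 with an estimated correlation). CYP71 genes (median 1.00, 1 of 7 rose) and SWEET sugar transporters (median 0.97, 2 of 6 rose) passed at adjusted p = 0.0152, and at adjusted p = 0.564 with an estimated correlation. The ribosomal protein median was -0.20 with no member past the threshold (adjusted p = 0.00146, and adjusted p = 0.842 with an estimated correlation). In all 1416 probe sets passed, 542 higher and 874 lower. The count was 3367 without zone 3 standard replicate 1, 198 without its replicate 2, 265 without zone 4 standard replicate 1 and 661 without its replicate 2. With array weights it was 328, and on the arrays of zones 3 and 4 alone limma called 0, with 2609 at an unadjusted p under 0.05. The 6 named decreases stayed called without any single array and the 6 named increases did not (adjusted p up to 0.333). Over all 4 zones on standard medium 12170 probe sets differed (limma F test).

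**Figure D3:**
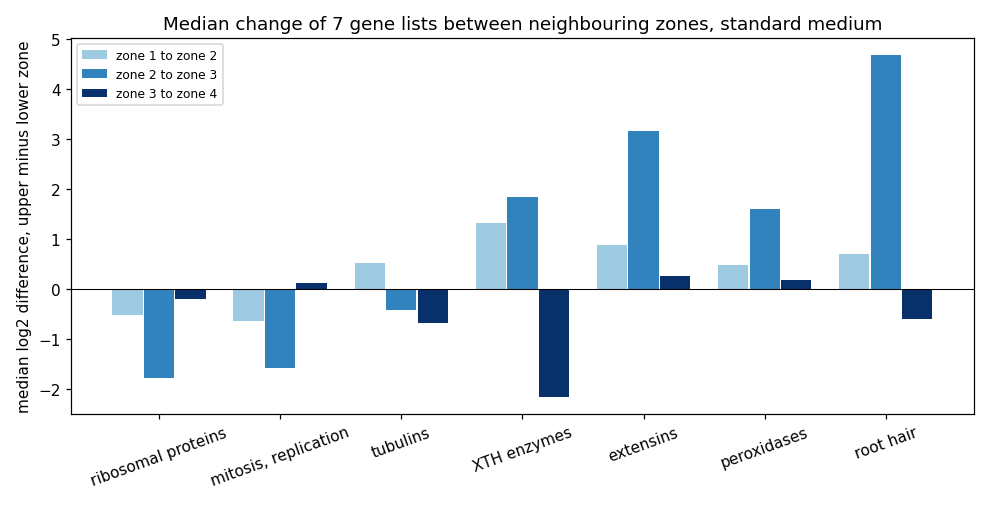
Median log2 difference of the measured members of 7 gene lists for the 3 steps between neighbouring zones on standard medium (bars start at 0). The root hair median rose by 4.68 and the ribosomal protein median fell by 1.78 from zone 2 to zone 3.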

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

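The tests of array position, scaling, RNA quality and handling below, and the comparison of lists between zones, were chosen after the main results had been seen, as was the count of other splits of the arrays. The test of the iron effect between zones was chosen before.

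The iron effect differed between zones by the interaction test itself for 8 named genes. The adjusted p-values were 0.000555 for AT1G73120, 0.000994 for AT5G38820 and for AT3G06890, 0.00279 for AT3G61930, 0.031 for BGLU42, 0.0317 for AT2G43610, 0.0434 for AT3G48450 and 0.0474 for AT4G10510. Between zones 4 and 1, the shift of a whole list differed for 6 lists (camera on the difference of the iron effects). The adjusted p was 1.21e-07 for coumarin synthesis (median difference 2.74, and adjusted p = 0.0126 with an estimated correlation), 0.000155 for iron regulators (median difference 0.40, adjusted p = 0.0664 with an estimated correlation) and 0.0393 for cell elongation (median difference -0.83, adjusted p = 0.344 with an estimated correlation). It was 3.17e-32 for the other iron-response genes (median difference 3.31, adjusted p = 0.00063 with an estimated correlation). Published work that may include studies of these samples gave that list. Its differences between zones, here and in the comparisons below, are therefore not independent evidence. It was 1.05e-33 for cytosolic ribosomal proteins and 0.0426 for plastid-encoded photosynthesis genes, with adjusted p = 0.294 and 0.874 with an estimated correlation. Between zones 4 and 3, iron regulators and cell elongation did not pass (adjusted p = 0.149 each), and coumarin synthesis did (adjusted p = 3.61e-05, and adjusted p = 0.0417 with an estimated correlation). The other iron-response genes (3.59e-09, and 0.047 with an estimated correlation), ribosomal proteins (4.2e-18, and 0.846) and plastid-encoded photosynthesis genes (0.00102, and 0.893) passed as well. Between zones 4 and 2, coumarin synthesis (adjusted p = 3.05e-08, and 0.00991 with an estimated correlation) and the other iron-response genes (6.29e-27, and 0.00122) passed both ways. Iron regulators (0.000204, and 0.0712), cell elongation (0.000702, and 0.108), ribosomal proteins (4.06e-31, and 0.343) and xyloglucan transglucosylases (0.0181, and 0.624) passed at the preset correlation only. Between zones 3 and 1, the other iron-response genes passed both ways (2.79e-18, and 0.00461), and iron regulators (0.0249, and 0.469) and ribosomal proteins (8.44e-05, and 0.848) at the preset correlation only.

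The median log2 difference of 109 cytosolic ribosomal protein genes was -0.70 in zone 4, with 7 called (camera adjusted p = 9.01e-37, and adjusted p = 0.25 with an estimated correlation). Scaling of the arrays was argued against, since under quantile normalization and median centring the median nearest to 0 was -0.57. RNA quality on the arrays with a low 25S control (standard replicate 2) or a high actin ratio (-Fe replicate 1) was argued against as the whole source, since the median was -0.77 without the former, -0.82 without the latter and -0.92 without both (-0.66 and -0.53 without standard replicate 1 and -Fe replicate 2). A -Fe piece taken from older tissue would also lower genes that fall from zone 3 to zone 4, and 200 such genes, chosen on 1 standard zone 4 array and measured against the other, had a median difference of -0.42 (-0.50 and -0.34 with the arrays exchanged). The ribosomal median itself was -0.20 from zone 3 to zone 4, but tissue above zone 4 was not analysed here, so a shift of the pieces cannot be told apart from an effect of iron supply or of time after transfer.

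For the genes called for iron over the 4 zones, other splits of the arrays were counted that kept 2 against 2 in each zone. Of 100 splits, drawn from 648, 1 gave as many calls, the real one at 232, and the highest of the others gave 80. This argues against chance as the whole source, as far as 100 splits can resolve. It does not address a difference that the arrays of a group share, such as the position of the pieces. Because the descriptions place the standard roots at 1 h after transfer, a handling response in them was weighed. It would leave early handling genes lower on -Fe medium. The 6 genes taken for this (PUB22, PUB23, PUB24, WRKY53, WRKY6 and WRKY22) had a median averaged difference of 0.14, ranging from 0.06 to 0.87. STZ (0.20 ± 0.28) was left out because its value had been seen before the prediction was written. Of the touch and wounding genes listed beforehand, 1 of 16 was measured. No array here shows that the 6 genes respond to transfer, so their values cannot settle whether a handling response was present. Of the 6, PUB23 alone passed, higher on -Fe medium (0.87 ± 0.17, limma adjusted p = 0.025). Roots of both media were cut at harvest, and a response to cutting was not separated from one to transfer. Differences between 1 h and 24 h are confounded with the medium and stay open, a handling response among them.

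The replicates of zone 3 on standard medium differed more than those of any other group. If the pieces had been taken at different positions, their difference should follow the gradient along the root. It correlated across genes with the difference between zones 4 and 2 on -Fe medium, measured on other arrays, at r = 0.54 (genes are not independent replicates), which is consistent with a difference in position. In zone 2 on standard medium the like value was 0.67, and in the same zones on -Fe medium 0.04 and -0.19. Background in dim probe sets was argued against as the whole source, since among 5119 bright probe sets the SD was 0.54, above the highest of the other groups (0.43). No biological explanation was tested.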

How the results depend on the processing

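The zone-specific replicate block and the alternatives for the second family of lists were chosen after the data had been seen, and the other tests before. No named call changed direction under any alternative. Of 296 calls of named genes, 203 were kept with only the arrays compared, 250 with array weights, 258 without an offset and 271 to 294 under the other planned settings (281 of 283 with the stricter filter). Leaving out each array of a comparison in turn lost more, 485 of 1616 named calls over all omissions together, with 1131 kept. The 5 lists set beforehand gave 11 calls over the 8 contrasts, against 7 with an estimated correlation. The second family gave 31 calls, against 3 with an estimated correlation and 18 with fry. The cause was not tested for the following changes unless it is stated. A 2-fold minimum left 117 of 232 averaged calls, which the minimum itself brings about. The zone-specific replicate block gave 444, and lost 7 of 96 named iron calls. For the interaction, values without an offset gave 10, a doubled offset 31 and the replicate block 35 (19 when fitted per zone), against 20, and the replicate block moved no other count by over 1.5 times and lost 2 of the 296 named calls. Array weights gave 26 for zone 2, 23 for zone 3 and 328 for the zone 3 to 4 step. With only the arrays compared, which leaves fewer arrays to estimate the spread, the counts were 0 for zone 1, 14 for zone 3, 5469 for the zone 2 to 3 step, 0 for the zone 3 to 4 step (unadjusted p under 0.05 for 520 and 2609 probe sets) and 15 for the overlap. The 520 for zone 1 are fewer than the share of 0.05 that chance alone would give among 16505 probe sets. Median centring moved the median of all probe sets by 0.11 in zone 2, 0.14 in zone 4 and -0.11 from zone 3 to 4.

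Leaving out each array in turn assumes that the lone array left varies like the other groups. The counts ran from 3 to 21 for zone 1, 6 to 17 for zone 2, 23 to 125 for zone 3, 63 to 88 for zone 4, 147 to 319 averaged, and 6 to 28 for the interaction. They ran from 310 to 3139, 5245 to 7965 and 198 to 3367 for the 3 zone steps, 11008 to 12443 over all zones, and 24 to 52 for the overlap. The lists gave 9 to 15 calls and the second family 24 to 39. With 2 arrays per group and no detection calls used here, probe sets near the offset are limited by background.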

Other observations

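The test of photosynthesis genes and that of iron-cofactor enzymes were chosen after PSAN, SAPX and SIR had been seen, and the lists were drawn up then.

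Nuclear genes of photosynthesis, which roots express at low levels, lay below their standard-medium signal on -Fe medium. TROL, a thylakoid membrane protein, fell by 1.14 on the log2 scale (SE 0.25, adjusted p = 0.04). The other members did not pass singly, with LHCB4.1 at -1.15 ± 0.49, PSBW at -1.12 ± 0.51 and PSAE-1 at -0.94 ± 0.55. The hypothesis that the group falls together was tested without PSAN and without the members of the tetrapyrrole list. All 16 measured members were negative, with a median of -0.78 (camera p = 9.27e-06, and p = 0.205 with an estimated correlation), so a common decline may be present but the test depends on the correlation between the genes. The second hypothesis, that genes of enzymes with iron cofactors fall as a group, was tested without SAPX and SIR. Of its 10 measured genes 7 were negative. The median was -0.33 (limma's camera p = 0.0532, and p = 0.0782 with an estimated correlation), and the cytochrome c gene CYTC-2 alone passed, at -0.64 ± 0.13 (adjusted p = 0.0303), so the test leaves it open.

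Some further lists of the second family passed for iron at the preset correlation and not with an estimated one. Ribosomal proteins had medians of -0.24 in zone 3 and -0.25 averaged (adjusted p = 1.65e-06 and 1.61e-17), and tetrapyrrole synthesis genes -0.36 and -0.22 (adjusted p = 0.0418 and 0.0338). Mitosis and replication genes had -0.40 in zone 3 (adjusted p = 0.00711), and class III peroxidases -0.27 in zone 1 (adjusted p = 0.00268). All of these ribosomal, mitosis and peroxidase calls were lost with fry, and the peroxidase call also without a filter. Leaving out zone 1 standard replicate 1 or zone 1 -Fe replicate 2 also lost the peroxidase call. The zone 3 mitosis call was lost without either zone 3 standard array and without zone 3 -Fe replicate 2. The zone 3 ribosomal call was lost without replicate 2 of either medium in that zone. Both lists fell from zone 2 to zone 3 on standard medium, so the position of the zone 3 pieces cannot be told apart here. The averaged tetrapyrrole call was also lost under quantile normalization, without a filter, with the stricter filter and without 5 of the 16 arrays, and the zone 3 call without a filter, with array weights, with fry and without 6 arrays. With an estimated correlation the adjusted p-values of these list calls ran from 0.56 to 0.982. The measured members of the lists of expansins (without EXPA7 and EXPA18), beta-glucosidases (without BGLU42, which rose), SWEET sugar transporters, auxin genes and plastid-encoded photosynthesis genes had averaged medians of 0.01, -0.14, 0.26, 0.07 and -0.07, with no member past the threshold (adjusted p from 0.239 to 0.97). The sign of the test differed from that of the median for expansins and the plastid-encoded genes, and both other scalings turned the latter median above 0. Among probe sets without a single named gene, 124 passed the averaged iron contrast, with differences up to 6.28 ± 0.34 and down to -4.38 ± 0.23.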
